A study of Mus musculus with 22 samples.

How the data were processed

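RNA abundance was measured on 22 Affymetrix arrays of the whole mouse genome, 14 of cultured aortic smooth muscle cells and 8 of aortic tissue. The cells came from mice lacking tenascin C (TNC) and were given no factor (3 arrays), tumour necrosis factor alpha (TNF, 10 ng/mL; 3 arrays), exogenous TNC (10 ug/mL; 4 arrays), or both (4 arrays). The tissue arrays hold RNA pooled over mice, 1 array for each combination of genotype (wild type, WT, or Tnc knockout, KO), segment (suprarenal or infrarenal aorta) and treatment. Untreated pools hold 5 mice each. Pools of mice given periaortic CaCl2 (0.5 M) on the infrarenal aorta and angiotensin II (1 ug/min/kg for 1 week), called CaAngII here, hold 8 mice each. The design text gives 24 h of TNF, while the sample labels of the cells count up from 23 h to 36 h, 1 h per array, and were not used. The titles of the group with TNC alone read "TNC or TNF", while its treatment label reads exogenous TNC, and the treatment label was followed. Replicate numbers of the cells do not pair arrays: the 19 pairs with the same number correlated, after group means were removed, at -0.014 to 0.057.

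The deposited values are intensity on a linear scale, 1 value for each of 45101 probe sets, from 0.037 to 39169. The authors name Affymetrix Expression Console as their software. Its version, algorithm and scaling target are not given in the sources used here. In the deposited table the mean of the middle 96% of probe sets is 499.8 to 499.9 on every array while the medians differ, so each array had been scaled to a common mean and no quantile normalization had been applied. All values are positive.

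The values were used as deposited, on a log2 scale with no pseudocount. After 64 control probe sets, 932 with several gene symbols and 9160 without a name were left out, 34945 probe sets stood for 18193 genes. The probe set with the highest mean over the 22 arrays stood for its gene. In the cells a gene was tested if it was at or above the 30th percentile of all probe sets in at least 3 arrays, which left 15639 genes. The 4 groups of cells were fitted together in limma 3.58.1 (R 4.3.3) with 10 residual degrees of freedom and moderated variances. There were 5 contrasts: TNF without TNC, TNF with TNC, TNC without TNF, TNC with TNF, and the difference of the TNF effects with and without TNC (interaction). A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. Adjusted p-values of single genes are limma's throughout. Changes are log2 with the standard error (SE) of the fit.

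Gene lists of known cell processes and cell types, 36 in all, were written by hand from textbook knowledge. The 35 with at least 3 tested members were tested in the cells with limma's camera at a fixed correlation of 0.01 between genes, adjusted over all lists and contrasts. The same test with a correlation estimated from the arrays and the fry test were run as alternatives. Members of a list were also counted with p-values adjusted over the list alone.

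The aortic comparisons have 1 array on each side, so they carry no test, no error and no p-value. Counts are of genes that differ at least 2-fold among those at or above the 50th percentile on at least 1 of the arrays compared. For each list the median log2 ratio was set against 10000 random lists of equal size, drawn from genes in the same 10 bins of mean expression. The percentile among these lists describes the list on that pair of pools and says nothing about other mice. Genes were also ranked by the smallest log2 ratio that 4 pairs of pools share in sign, and 12.5% of genes share a sign over 4 pairs by chance. Genes that TNC moved in the cells under TNF were followed in the aorta as lists.

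Nothing in the labels states that replicate arrays come from separate cultures, so the p-values measure only the spread between these samples. The contrasts, filters, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule names Tnc, the 12 largest called rises and falls of each cell comparison whose arrays did not overlap between groups, the 12 lowest adjusted p of each sign for the interaction, the 10 genes at each end of each ranking over 4 pairs of pools, the 12 largest differences each way for the suprarenal genotype comparisons under CaAngII, up to 5 members of each list, and 19 genes fixed in advance. Genes outside it are marked as chosen after their values were seen.

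The code was tested on simulated data in which 200 of 15639 genes were given changes of 1 or 2 on the log2 scale. At a change of 2, 75 to 82% were called, at a change of 1, 56 to 73%, and 3.6 to 4.76% of calls were false. The correlation between replicate arrays was 0.962 to 0.969, and the median SD of a gene within groups was 0.13 to 0.18 on the log2 scale, higher for dim genes.

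Alternatives were quantile normalization, centring on the median, no filter or a stricter one, other choices of probe set, log2(value + 32), other variance models, the replicate number or culture as a block, a 2-fold minimum, and leaving out each cell array in turn. For the culture block, arrays of the same number within a TNC condition were taken as the same culture, which no label states. For the aorta they included no filter and stricter filters. Tests and most tables ran in R 4.3.3. Data preparation ran in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Left out were gene-level tests in the aorta, because no condition has a replicate, and pathway databases, because none was available.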

Results

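Tenascin C is a large glycoprotein of the extracellular matrix that arteries make at sites of injury and mechanical load. The series asks what its loss changes in the aorta and what adding it back changes in smooth muscle cells. In the aorta, Tnc signal was 1805 in untreated WT suprarenal tissue and 257.5 in the matching KO pool, a log2 ratio of -2.81. Under CaAngII the suprarenal values were 2327 and 488.7 (log2 -2.25). The infrarenal values were 2453 against 336.4 untreated and 2699 against 441.4 under CaAngII (log2 -2.87 and -2.61), 1 pool each. The cells, all from KO mice, ranged from 66.26 to 144.2 over 14 arrays. A second, dimmer Tnc probe set was lower in KO pools only without treatment (log2 -1.44 suprarenal and -1.28 infrarenal, against 0.56 and -0.06 under CaAngII).

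**Figure D1:**
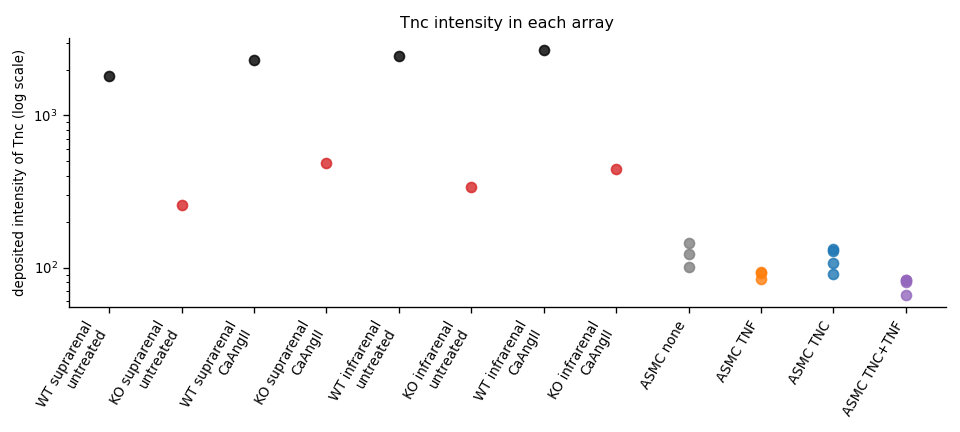
Tnc signal (deposited intensity) of each pool and each cell array, 1 point per array.

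TNF is a cytokine that drives inflammatory gene expression through NF-kB. In cells without TNC it raised Ccl2 from 827.8 to 18680 (log2 change 4.50, SE 0.11, adjusted p = 1.31e-10, 3 arrays against 3) and Il6 from 462.6 to 6339 (3.78, SE 0.15, adjusted p = 5.63e-09). Cxcl10 rose by 7.35 (SE 0.32, adjusted p = 1.29e-08) and Cxcl9 by 10.79 (SE 0.43, adjusted p = 6.57e-09). Cxcl9 started near background at 1.743, and its change on the scale of log2(value + 32) was 6.52. The adhesion genes Icam1 (1.85, SE 0.08) and Vcam1 (1.05, SE 0.09) rose as well. Elastin and contractile genes went down: Eln fell by 3.41 (SE 0.25, adjusted p = 9.34e-07), and the changes of Myh11 and Myl9 were -2.27 (SE 0.21) and -2.63 (SE 0.09). Acta2 fell by 0.53 (SE 0.06, adjusted p = 3.3e-05), from 22930 to 15860. In all, 5335 of 15639 genes were called, 2200 higher and 3135 lower (2973 and 2323 with each array centred on its median). Over all genes, called or not, the arrays of the groups did not overlap in 49.6%, against a chance share of 10%. At least 2-fold, 672 were higher and 785 lower.

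Interferon response genes, which cells switch on against viruses, rose throughout under TNF without TNC: 32 of 32, with a median of 3.42 (adjusted p = 3.93e-33, or 0.0381 with an estimated correlation). Ifit2 rose by 4.29 (SE 0.08), Gbp3 by 3.75 (SE 0.08) and Irf1 by 3.02 (SE 0.06). All 20 NF-kB pathway genes rose (median 2.13), among them Nfkbie by 4.59 and Birc3 by 3.61, as did all 13 genes of MHC class I and antigen processing (2.89), among them Psmb8 by 4.28 and Tap2 by 2.19. Of 28 chemokines and cytokines 19 rose and 1 fell (20 and 2 when adjusted over the list alone), and of 13 complement and acute phase genes 8 rose, Saa3 by 7.89. The contractile list fell, with 18 of 26 members lower (19 over the list alone; median -1.16; adjusted p = 9.78e-09, and adjusted p = 0.0621 with an estimated correlation). Also past the fixed-correlation test, and not past the estimated one, were the rises of adhesion molecules (8 of 10 up, 1 down; adjusted p = 0.0621 with an estimated correlation), glycolysis (13 of 19 up, Hk2 by 1.03; 0.0895) and antioxidant genes (7 of 16 up, Sod2 by 2.06; 0.0788). So were the falls of cartilage and bone genes (12 of 17, Sox9 by -2.03; 0.054), cell cycle genes (16 of 48, Ccne2 by -1.65; 0.718) and fatty acid oxidation genes (7 of 19, Acadm by -1.06; 0.299). The unfolded protein response list, with 3 of 22 members up, had adjusted p = 0.0478, and adjusted p = 0.778 with an estimated correlation.

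With TNC present, TNF raised Csf2, a growth factor for granulocytes and macrophages, from 61.37 to 2176 (log2 change 5.15, SE 0.49, adjusted p = 2.19e-05, 4 arrays against 4). Ubd rose by 4.19 (SE 0.27, from 29.2, or 3.19 on the scale of log2(value + 32)), Cxcl10 by 3.94 (SE 0.28) and Ccl20 by 3.64 (SE 0.18). Ccl2 rose by only 0.37 (SE 0.10, adjusted p = 0.0178), from 16040 to 20670, and Il6 by 0.92 (SE 0.13, adjusted p = 0.000381), from 11340 to 21370. The matrix protease gene Mmp9 rose by 3.30 (SE 0.52, adjusted p = 0.000913), from 10.9 to 107.2, or by 1.64 on the scale of log2(value + 32). Acta2 fell by 0.37 (SE 0.05), Tagln by 0.54 (SE 0.06) and Eln by 0.94 (SE 0.21). Cyp24a1 fell by 3.40 (SE 0.19), and Fgf18 fell to 13.62, near background (-1.70 on the scale of log2(value + 32)). The called genes numbered 3402, 1474 higher and 1928 lower (1907 and 1557 with each array centred on its median), with 276 and 296 at least 2-fold. Over all genes the groups did not overlap in 23.1% (chance share 2.86%).

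Under TNF with TNC interferon, MHC class I, NF-kB and chemokine genes rose again, while complement and acute phase genes did not pass (2 of 13 up, 1 down; median 0.13; adjusted p = 0.208). Interferon genes were up in 30 of 32 (31 over the list alone; median 1.45; adjusted p = 1.09e-28, or 0.0482 with an estimated correlation), with Gbp2 up by 2.11 and Irf1 by 1.39. MHC class I genes were up in 13 of 13 (median 1.07, Psmb8 by 2.08), NF-kB genes in 16 of 20 (17 over the list alone; median 0.70) and chemokines in 13 of 28 (16 over the list alone; median 0.85). Genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, were up in 18 of 22 (21 over the list alone; adjusted p = 9.3e-09, and adjusted p = 0.355 with an estimated correlation), with Hsp90b1 up by 0.47. Cholesterol synthesis genes were up in 11 of 19 (0.268 with an estimated correlation; Insig1 by 0.82), and contractile genes were down in 17 of 26 (adjusted p = 1.78e-08, and 0.0655 with an estimated correlation). TGF-beta response genes were down in 13 of 23 and up in 5 (0.435 with an estimated correlation), with Ccn2 falling by 0.83 and Tgfb2 by 0.97. Collagen and elastic fibre genes were down in 10 of 34 and up in 4 (0.625 with an estimated correlation), Col8a1 falling by 0.94, and endothelial genes were down in 8 of 18 and up in 1 (0.354), Vwf falling by 1.06. Adhesion molecules (6 of 10 up, 1 down; 0.13), prostaglandin synthesis (6 of 14 up, 1 down; 0.111; Ptgs2 by 1.59), cartilage and bone (5 of 17 down; 0.13) and fatty acid oxidation (5 of 19 down; 0.275) also passed at the fixed correlation alone.

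TNC given without TNF raised inflammatory genes, and a substance carried with its preparation cannot be told apart from TNC here. Il6 rose from 462.6 to 11340 (log2 change 4.62, SE 0.14, adjusted p = 1.22e-09, 4 arrays against 3), Ccl2 by 4.28 (SE 0.10, adjusted p = 2.03e-10) and Cxcl1 by 3.32 (SE 0.07, adjusted p = 5.81e-11). Lcn2, an iron-binding acute phase protein, rose from 25.22 to 23670 (9.88, SE 0.12, adjusted p = 9.86e-13, or 8.69 on the scale of log2(value + 32)), from near background to near the top of the arrays' range. The metalloproteinase genes Mmp3 (4.26, SE 0.14) and Mmp13 (8.51, SE 0.68, from 4.18, or 5.33 on the scale of log2(value + 32)) rose along with the inhibitor gene Timp1 (2.09, SE 0.07), while Timp3 fell by 1.85 (SE 0.13). Eln fell by 4.31 (SE 0.23, adjusted p = 1.29e-07), from 8634 to 434.3, and Myh11 by 2.68 (SE 0.20). Wfdc17 rose by 10.69 (SE 0.15) from a signal of 2.989, or by 7.14 on the scale of log2(value + 32). Acta2 changed by -0.14 (adjusted p = 0.0735), Vcam1 by 0.14 (0.267) and Cxcl10 by -0.77 (0.0741), all short of the threshold. The called genes numbered 4926, 2498 higher and 2428 lower (461 and 543 at least 2-fold). Over all genes the groups did not overlap in 40.5% (chance share 5.71%).

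NF-kB genes rose under TNC in 19 of 20 (median 1.26; adjusted p = 1.78e-19, or 0.0108 with an estimated correlation), chemokines in 19 of 28 with 2 down (3 over the list alone; median 2.64), and complement and acute phase genes in 10 of 13 (median 2.16), with Hp up by 4.63 and Cfb by 4.54. The interferon list did not pass (adjusted p = 0.377; median -0.21; 4 of 32 up and 9 down, 10 over the list alone), with Mx1 up by 2.23 and Ifit3 down by -1.49. Cell cycle genes fell in 39 of 48 (43 over the list alone; median -1.12; adjusted p = 1.18e-13, and adjusted p = 0.268 with an estimated correlation), Mcm6 by -0.99 and Nuf2 by -1.61. Cholesterol synthesis genes fell in 16 of 19 (0.203 with an estimated correlation), Idi1 by -1.72 and Sqle by -1.33. Contractile genes fell in 17 of 26 (18 over the list alone; adjusted p = 0.0992 with an estimated correlation), Itga8 by -2.35, and cartilage and bone genes in 9 of 17 (0.0563), Col10a1 by -2.12. Glycolysis and hypoxia genes rose in 14 of 19 with 2 down (0.054 with an estimated correlation), Adm by 2.20 and Hk2 by 1.60. Metalloproteinases and inhibitors rose in 14 of 33 with 4 down (0.054), and unfolded protein response genes in 14 of 22 (19 over the list alone; 0.435), Chac1 by 1.36. Rises of MHC class I (9 of 13; 0.0877; H2-K1 by 1.07), antioxidant (9 of 16 up, 2 down; 0.0621), adhesion (6 of 10 up, 2 down; 0.185) and endothelial genes (9 of 18; 0.299; Ecscr by 1.17), and the fall of basement membrane collagens (5 of 7 down, 1 up; 0.213), passed at the fixed correlation alone.

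When TNF was present on both sides, TNC lowered interferon genes and raised granulocyte growth factors. Cxcl10 fell from 12070 to 665.2 (log2 change -4.18, SE 0.30, adjusted p = 2.5e-06, 4 arrays against 3), Cxcl9 by 5.05 (SE 0.40) and Ifit2 by 3.75 (SE 0.08, adjusted p = 3.5e-10). Csf2 rose by 6.80 (SE 0.53, adjusted p = 4.19e-06), Csf3 by 6.47 (SE 0.52) and Cxcl5 by 6.53 (SE 0.19, adjusted p = 6.83e-09). Csf2 had a signal of 19.51 without TNC, and its change on the scale of log2(value + 32) was 5.37, against 4.50 for Csf3. Il6 rose by 1.75 (SE 0.14), Mmp3 by 2.98 (SE 0.14), Mmp13 by 5.36 (SE 0.68) and Mmp2 by 0.61 (SE 0.06), and Eln fell by 1.85 (SE 0.23). Ccl2 changed by 0.15 (adjusted p = 0.341) at signals close to the top of the range, and Acta2 by 0.01 (0.889). The called genes numbered 4372, 2521 higher and 1851 lower (2034 and 2195 with each array centred on its median; 347 and 400 at least 2-fold). Over all genes the groups did not overlap in 35.8% (chance share 5.71%).

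All 32 interferon genes were lower with TNC under TNF (median -1.98; adjusted p = 2.08e-29, or 0.0466 with an estimated correlation), Igtp by -2.73 and Gbp3 by -1.74. MHC class I genes were lower in 10 of 13 (median -0.95; 0.0447 with an estimated correlation), Tap1 by -1.98 and Psmb8 by -1.45. Unfolded protein response genes were higher in 21 of 22 (median 0.84; adjusted p = 1.95e-11, and adjusted p = 0.279 with an estimated correlation), Herpud1 by 1.84, Chac1 by 2.08 and Xbp1 by 0.51. Cell cycle genes were lower in 16 of 48 (17 over the list alone; 0.487 with an estimated correlation), Mcm6 by -1.61, and cholesterol synthesis genes in 7 of 19 (0.434), Idi1 by -0.94. Glycolysis genes were higher in 9 of 19 and lower in 1 (0.275), and chemokines higher in 11 of 28 and lower in 7 (13 and 7 over the list alone; 0.355), with Il15 falling by 2.53.

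The TNF effect itself differed with and without TNC in 2897 genes, 1506 with a higher and 1391 with a lower effect in the presence of TNC (1159 and 1634 with each array centred on its median; 398 and 482 at least 2-fold). For Ccl2 the difference was -4.13 (SE 0.15, adjusted p = 2e-08), for Il6 -2.86 (SE 0.20, adjusted p = 2.44e-06) and for Ifit2 -3.36 (SE 0.11, adjusted p = 9.35e-09), so TNF raised each of them less when TNC was there. The acute phase genes Lbp (-6.08, SE 0.13, adjusted p = 4.68e-10), Lcn2 (-6.49, SE 0.17) and Hp (-4.29, SE 0.18) behaved alike. Eln (2.46, SE 0.33, adjusted p = 0.000339), Myh11 (1.62, SE 0.28) and Myl9 (1.26, SE 0.12), which TNF lowered, fell less with TNC. TNC alone had already lowered them, Eln from 8634 to 434.3 and Myh11 from 340.8 to 53.29. With both factors Eln (225.6 against 814.3) and Myh11 (33.91 against 70.43) read lower than with TNF alone, and Myl9 higher (2601 against 2046). Part of the smaller fall of Myh11 can come from its dim signal. Csf2 (3.67, SE 0.75, adjusted p = 0.00548) and Mmp9 (2.97, SE 0.80, adjusted p = 0.0241; 1.53 on the scale of log2(value + 32)) had larger TNF effects with TNC. Part of the smaller rise of Ccl2, Lcn2 and Cxcl1 can come from signals near the top of the range, since the brightest probe set of a cell array read 26914 to 33291.

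By list, the TNF effect was smaller with TNC for interferon genes (27 of 32 lower, 30 over the list alone; median -1.66; adjusted p = 4.61e-26, and adjusted p = 0.054 with an estimated correlation), NF-kB genes (18 of 20; median -1.23; 0.0108), MHC class I genes (12 of 13; median -1.44; 0.0108), complement and acute phase genes (8 of 13; median -1.46) and chemokines (15 of 28 lower, 2 higher; median -1.04). The contractile list had the opposite sign, with 8 of 26 higher (11 over the list alone; median 0.40; adjusted p = 0.203 with an estimated correlation). So did basement membrane collagens (6 of 7 higher; 0.0621), with Col4a2 at 0.60 and Col4a1 at 0.49, and cell cycle (10 of 48 higher, 1 lower; 0.591), cholesterol synthesis (6 of 19 higher; 0.457; Cyp51 at 1.17) and cartilage genes (3 of 17 higher; 0.185). Glycolysis (11 of 19 lower, 2 higher; 0.121), adhesion (6 of 10 lower, 1 higher; 0.114; Icam1 at -1.26), antioxidant (5 of 16 lower, 1 higher; 0.121) and endothelial genes (4 of 18 lower; 0.279) were on the negative side.

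TNF and TNC moved many genes the same way. Of the genes TNF raised, 1281 were also raised by TNC alone, where 351.4 would be shared by independent calls, and 1521 were lowered by both (486.7 expected). Both effects are measured against the same 3 unstimulated arrays, so part of this excess can come from the shared controls: the covariance of the effects was 0.373, and 0.0916 in simulations where only the noise of the controls was shared. TNF raised 838 genes both without and with TNC (207.4 expected) and lowered 1155 both ways (386.5 expected). Among the 2200 genes TNF raised without TNC, 654 (29.7%) were lower with TNC under TNF (260.4 expected), among them Cxcl9, Cxcl10 and Ifit2, and 414 (18.8%) were higher (354.6 expected). Both comparisons use the same 3 arrays with TNF alone, with opposite sign, so part of this excess can come from the shared arrays: the covariance was -0.154, and -0.0921 in simulations with only the shared noise.

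**Figure D2:**
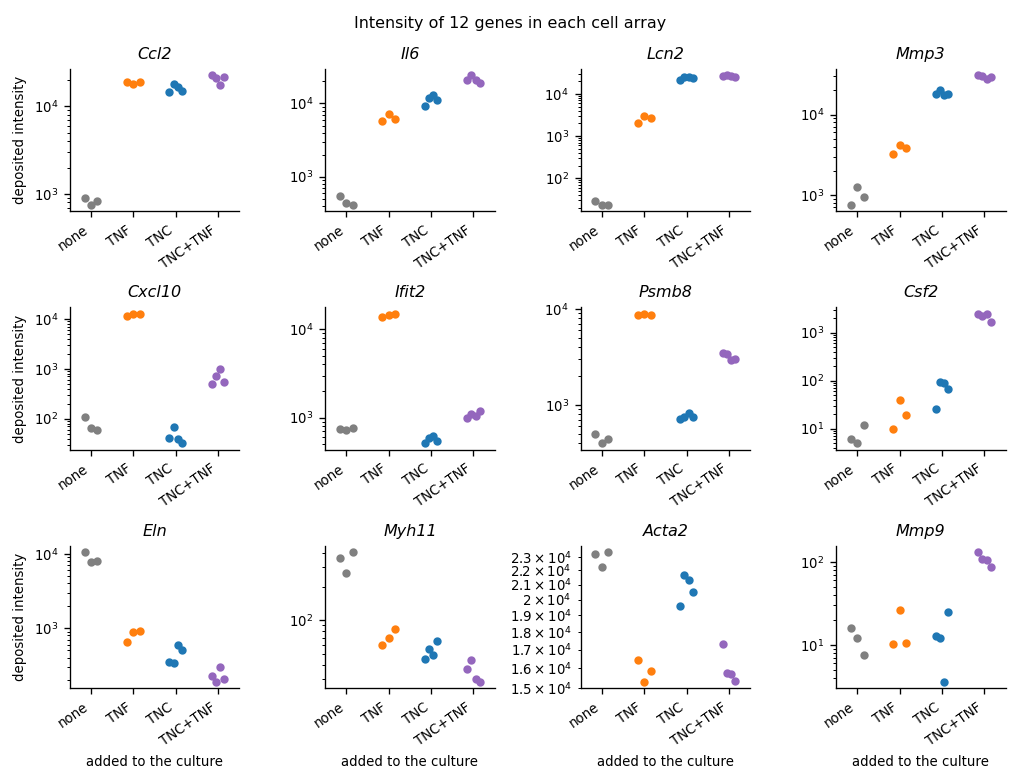
Signal of 12 genes on each of the 14 cell arrays, by group.

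**Figure D3:**
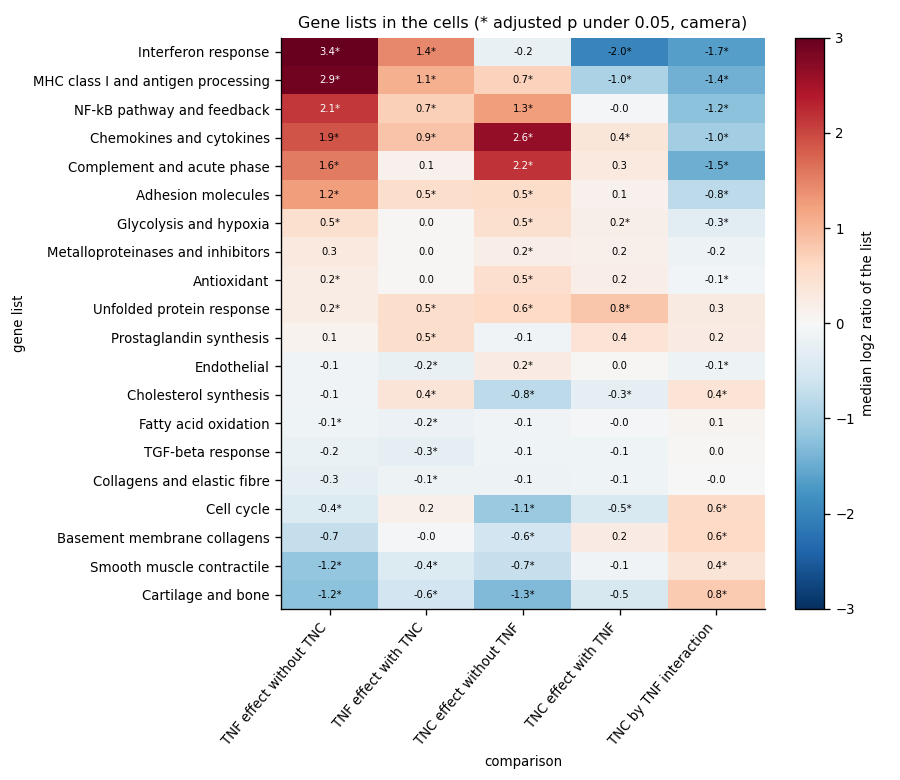
Median log2 change in the 5 comparisons of the cells, for the gene lists that passed the fixed-correlation test in any of them.

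In the infrarenal aorta, where CaCl2 was applied, CaAngII pools held more transcripts of macrophages, the phagocytes that enter injured arteries. Trem2 was higher by 6.69 on the log2 scale in WT and 6.88 in KO, and Fcgr1 by 3.62 and 3.47, 1 pool against 1. Trem2 read 12.63 and 12.24 without treatment, near background, and its ratios on the scale of log2(value + 32) were 4.90 and 5.05. Macrophage genes were at least 2-fold higher in 22 of 24 in WT (median 2.42) and 23 in KO (median 2.74). Mmp13 (7.98 in WT and 7.89 in KO, or 6.74 and 6.48 on the scale of log2(value + 32)) and Mmp12 (4.55 and 5.76) were higher in both genotypes, with Col11a1 (4.08 and 4.04), Thbs2 (3.44 and 3.17) and Fbn2, which read 37.06 and 33.43 without treatment (3.62 and 3.75 on the same scale). Smooth muscle genes were lower: Myocd by -2.10 in WT and -3.13 in KO, and Kcnmb1 by -2.27 and -1.98. None of the aortic differences was tested, since each condition has 1 pool. At least 2-fold, 1245 genes were higher and 818 lower in WT, and 1298 and 725 in KO.

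By list, chemokines had infrarenal medians of 2.66 in WT and 2.35 in KO, with Cxcl2 at 3.76 and 3.38 on the scale of log2(value + 32). Interferon genes stood at 1.74 (26 of 32 at least 2-fold higher) and 1.21 (19 of 32), with Mx1 at 3.52 and 2.67. Collagens and elastic fibre genes stood at 1.06 (18 of 35 at least 2-fold higher) and 1.01 (20), Col12a1 at 2.74 and 2.61. Cell cycle genes had medians of 1.36 (25 of 35) and 1.04 (19 of 33), with Mki67 at 1.72 and 1.59 and Cdk1 at 1.95 and 0.77, while Foxm1 was at -1.01 in KO. NF-kB genes stood at 1.10 and 1.36, with Nfkbie at 2.56 and 2.38, and lymphocyte genes at 2.16 and 1.63, with Ighm at 3.99 and 4.14. On the lower side were contractile genes (-1.09, 14 of 26 at least 2-fold lower, and -0.87, 10 of 26), fatty acid oxidation (-1.22 and -1.02) and adipocyte genes (-1.54 and -1.14), with the brown-fat gene Ucp1 at -3.87 and -4.06. Of the lists, 28 of 35 in WT and 25 of 34 in KO lay outside the central 95% of random lists, where 1.75 and 1.7 would by chance.

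The suprarenal aorta, which received no CaCl2, gave smaller differences in WT. Col8a1 was higher by 1.44, Col12a1 by 1.34 and Comp by 1.43 in the WT CaAngII pool, and Saa1 went from 45.78 to 399.9. In KO, chemokines were far higher: Ccl2, which draws monocytes, by 5.95 and Cxcl1 by 5.46. Cxcl2 went from 3.544 to 6002 and Cxcl5 from 4.283 to 2848, from background, so their ratios are given on the scale of log2(value + 32), as 7.41 and 6.31. The neutrophil genes S100a8 (5.44), S100a9 (6.09) and Csf3r (3.84) were higher in the KO pool as well, while S100a9 was lower in the WT pool (-2.15). The skeletal muscle genes Tnni2 (-4.325 in WT and 2.804 in KO) and Myh4 (-3.497 and 3.48) had opposite signs too, while Tcap was lower in both (-2.026 and -1.11). Col8a1 (1.49) and Col12a1 (1.44) differed by about as much in KO as in WT. Lymphocyte genes were at least 2-fold lower in 12 of 15 in each genotype (medians -2.16 and -2.23), Ms4a1 by -3.70 in WT and -3.81 in KO, while Ighm was 1.45 higher in WT. The counts at 2-fold were 140 higher and 275 lower in WT, against 426 and 179 in KO. Over genes at or above the 50th percentile in the cells alone the WT direction turned, with 99 higher and 86 lower. List medians for chemokines were 0.35 in WT and 2.68 in KO, for collagens 0.51 and 0.56, and for contractile genes -0.24 and -0.12.

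Over all 4 CaAngII pairs, both genotypes and both segments, 57 genes were at least 2-fold higher and 5 at least 2-fold lower among 12632. The acute phase gene Saa3 led with a smallest ratio of 3.85, and Thbs1 (2.10), Esm1 (1.99) and Timp1 (1.96) were among the 10 highest. Mmp13, Gpr35, Arg1, Syndig1 and Il6 were among them too, but read near background in untreated pools. On the scale of log2(value + 32) their smallest ratios were 1.46, 1.23, 1.57, 1.18 and 1.56, below the 2.02 of Thbs1. On the lower side were Tcap (-1.11) and Vwc2 (-1.08), with the clock gene Per2 at -0.87 and the fat hormone gene Lep at -0.78. Pate4 and Smtnl1 ranked below them, but their smallest ratios lie between signals near background (-0.48 and -0.51 on the scale of log2(value + 32)). A sign was shared by 2077 genes on the higher side and 1897 on the lower.

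Under CaAngII, the suprarenal KO pool held far more transcripts of neutrophils and of the chemokines that draw them than the WT pool. S100a9 read 15180 in KO and 276.4 in WT (log2 5.78), S100a8 17380 and 475.3 (5.19), and Cxcl2 6002 and 24.1 (7.96, or 6.75 on the scale of log2(value + 32)). Il6 (4526 against 196.8) and Ccl2 (4320 against 188.3) both differed by 4.52. Cxcl3, Cxcl5, Acod1, Cd177 and Cxcr2 read under 30 in WT, near background, and differed by 7.53, 5.58, 3.31, 3.76 and 4.44 on the scale of log2(value + 32). The protease genes Mmp8 and Mmp9 differed by 2.80 and 2.40. The matrix gene Thbs1 was 2.28 higher. On the lower side were the steroid gene Hsd3b1 (1425 in WT and 11.4 in KO; -5.07 on the scale of log2(value + 32)), Hao2 (172.8 and 2.233; -2.58 on that scale) and the clock-controlled gene Dbp (-2.97). At least 2-fold, 297 genes were higher in KO and 37 lower. The list median was 5.19 for the 5 neutrophil members counted, of 12 on the array. Genes bright in KO alone count, such as Cxcr2 (1068 against 18.75), so this median leans toward genes high in KO. Camp, Ltf and Ngp, under the filter, read 43.55 against 40.42, 71.08 against 33.06 and 67.09 against 61.1. Other list medians were 2.04 for chemokines (14 of 24 at least 2-fold higher), 0.57 for macrophages, 0.14 for interferon genes, -0.13 for collagens and -0.21 for contractile genes. Skeletal muscle genes differed too (median 1.29).

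**Figure D4:**
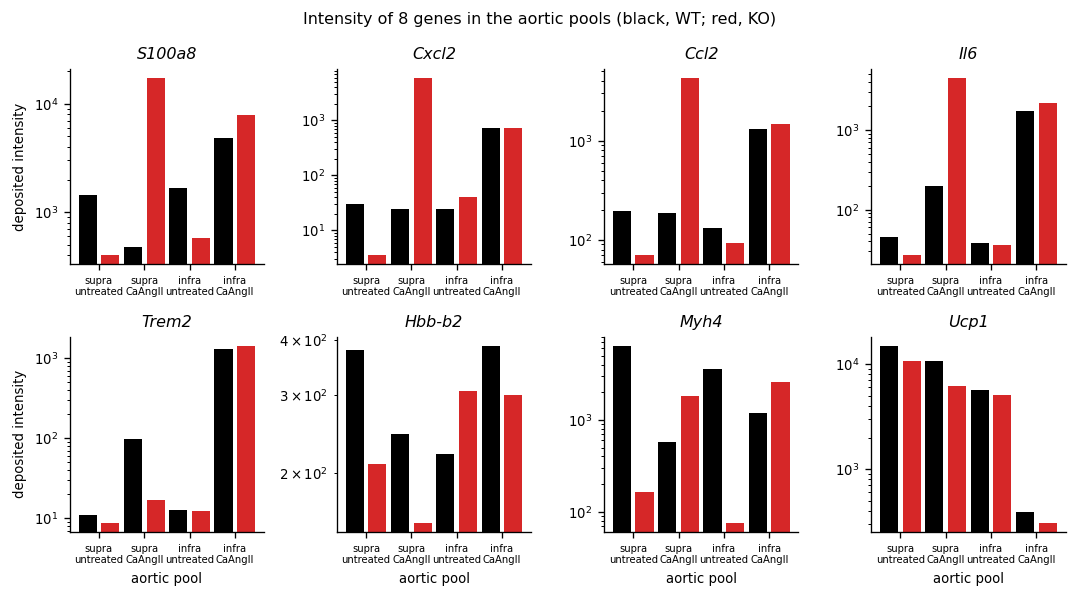
Signal of 8 genes in the 8 aortic pools, 1 array each.

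Without treatment, skeletal muscle and neutrophil genes were lower in KO pools than in WT pools. Myh4 was lower by -5.30 suprarenally and -5.58 infrarenally, and Tnni2 by -5.29 and -4.72. S100a9 was lower by -2.46 and -2.09. Ccl2 was lower by -1.48 in the suprarenal pool and Cxcl1 by -1.19 in the infrarenal pool. The list medians were -4.62 and -3.83 for skeletal muscle and -1.83 and -1.61 for neutrophils, while collagens (-0.22 and -0.08) and chemokines (-0.37 and -0.19) stood closer to 0. At least 2-fold, 60 genes were higher and 149 lower suprarenally, and 119 and 76 infrarenally. The infrarenal share of higher genes was 61%, and 50.2% under quantile normalization. The steroid genes Hsd3b1 and Cyp11b1 were higher in the infrarenal KO pool (2613 against 8.751 and 1012 against 58.32). Svs6 and Pate14 were high there too (745.5 against 31.75 and 528.5 against 19.22). Such genes may come from other tissue taken with the aorta in that pool, which was not tested.

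In the infrarenal CaAngII pools, interferon genes were lower in KO than in WT in 32 of 32 members, by a small amount (median -0.42, lower than all 10000 random lists). Oasl1 stood at -0.74, Cmpk2 at -0.73, Ifit2 at -0.70 and Mx1 at -0.69, and the interferon-driven chemokine gene Cxcl10 at -0.82. Chemokines as a list were near 0 (median -0.15), as were NF-kB genes (-0.11), collagens (0.11) and macrophages (-0.03). The heat-shock gene Hspa1a was 1.66 higher in KO. Other tissue genes differed by more between these pools: Cpb1 read 10590 in WT and 1682 in KO, Ms4a1 stood at -1.15, and skeletal muscle genes were higher in KO (median 1.15, 10 of 14 at least 2-fold). In all, 65 genes were at least 2-fold higher and 70 lower. Over all 4 genotype pairs, Tnc was the lowest (largest shared ratio -2.25). Rimklb, Ksr2 and Dmbt1 were among the 5 lowest, but read near background in several pools, and stood at -0.96, -0.55 and -0.13 on the scale of log2(value + 32). Alad was higher in KO by 0.75 to 1.29, from 600.9 to 1111 in WT pools and 1474 to 2245 in KO pools. Pate14 and Svs6 ranked above it, but read at most 19.22 and 31.75 in 7 of the 8 pools, near background, so their rank carries little. At least 2-fold in all 4 pairs was 1 gene higher and 2 lower. Of 12632 genes, 619 shared a sign on the higher side and 867 on the lower, together no more than the 12.5% that would by chance.

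The CaAngII response of KO pools minus that of WT pools repeats these contrasts against the untreated pools. Suprarenally it was 8.23 for S100a9. For Cxcl2, Cxcl3 and Hsd3b1, which read near background in some of the pools, it was 7.56, 7.84 and -5.17 on the scale of log2(value + 32). The list medians were 4.39 for neutrophils, 2.04 for chemokines, 5.75 for skeletal muscle and -0.15 for interferon genes. Infrarenally it was 2.51 for S100a9, -1.11 for Cmpk2 and -0.94 for Ifit2, with medians of 2.23 for neutrophils, -0.06 for chemokines, 4.97 for skeletal muscle and -0.48 for interferon genes. The counts at 2-fold were 472 higher and 242 lower suprarenally, and 220 and 318 infrarenally. Quantile normalization turned the infrarenal majority, from 40.9 to 57.5% higher. Each of these rests on 4 pools and was not tested.

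**Figure D5:**
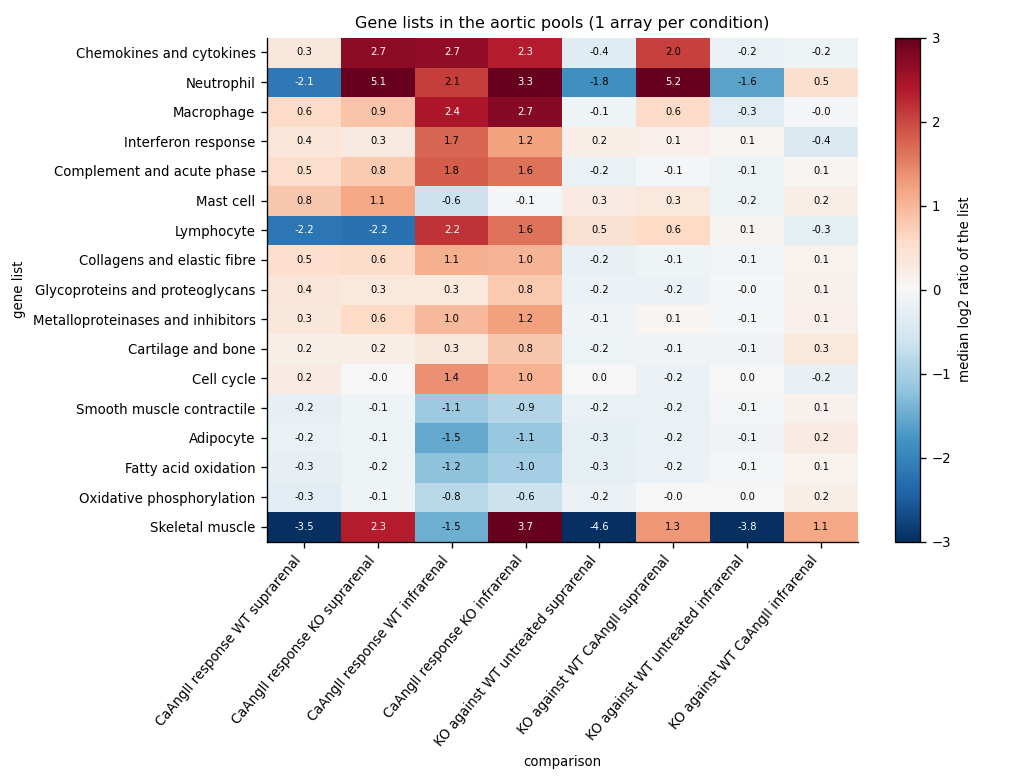
Median log2 ratio of selected gene lists in the direct comparisons between aortic pools, without the genotype differences in response.

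Some genes differed between the infrarenal and suprarenal segments in all 4 pairs, and no gene list was tested for them. The antisense transcript Hoxa11os of the posterior Hox cluster was higher infrarenally in all 4 pairs, as were Mkx, Htr2b, Vip and the pancreatic gene Cpb1. All of them read near background in at least 1 suprarenal pool, and their smallest ratios on the scale of log2(value + 32) were 1.03, 1.07, 1.21, 1.14 and 1.38. Genes higher suprarenally included Cpne9, Stmn4 and Celsr3, known from neurons, which read under 20 in every infrarenal pool (-1.77, -2.66 and -2.02 on that scale). At least 2-fold in all 4 pairs were 50 genes higher infrarenally and 477 higher suprarenally.

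Genes that TNC moved in the cells under TNF, taken as whole lists, differed little in the aorta between genotypes. In the infrarenal CaAngII pools the 2326 genes TNC had raised stood at a median of 0.05 in KO against WT (random lists 0.02 to 0.04), and the 1675 it had lowered at -0.01 (random lists 0.02 to 0.04), each beyond all 10000 random lists. In the suprarenal CaAngII pools the medians, -0.03 and -0.04, lay inside the range of random lists. Of 12 such medians, 7 lay outside the central 95%, all of them within 0.11 of 0. In the infrarenal CaAngII pools, loss of the effect seen in the cells would give the opposite signs. With only the 100 genes of lowest p each way, the lowered genes there stood at -0.164 and the raised ones at 0.047, inside the random range. The lowered genes stood at -0.15 and -0.177 for the suprarenal and infrarenal genotype difference, but at 0.102 in untreated suprarenal pools.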

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

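The tests of the 3 patterns weighed here were chosen only after the results were seen, and the counts of other splits of the arrays were planned.

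The TNF effect differed with and without TNC in 2897 genes. In all, 11 named genes were called for TNF both without and with TNC, with opposite sign and with differences of 0.495 for Col4a1, 0.597 for Col4a2, 1.17 for Cyp51, 1.91 for Ifi27, -0.627 for Mcm6, 0.581 for Mmp2, -0.696 for Pecam1, 2.76 for Plagl1, -5.10 for Serpina3n, -2.57 for Serpinb1a and -8.49 for Wfdc17, which read 2.989 in unstimulated cells (-5.02 on the scale of log2(value + 32)). Of 100 drawn splits of the 14 arrays into groups of the same sizes, 1, the real one, gave as many genes as the interaction, and the highest other gave 1717. Of the 35 splits of each other comparison with 4 arrays in a group, 1, the real one, gave as many genes: TNF with TNC 3402 (highest other 2), TNC without TNF 4926 (highest other 1350) and TNC with TNF 4372 (highest other 1892). For these 4 results none of the other splits tried gave as many genes. For the 3 comparisons of 2 groups this argues against a random grouping of the arrays. The splits drawn for the interaction mix all 4 groups, so the TNF and TNC effects enter their spread. They cannot speak for an interaction apart from those effects. Splits cannot exclude differences between cultures or batches, since nothing states that replicate arrays are separate cultures. For TNF without TNC, 3 arrays against 3 make 10 splits, 1 of them the real one, too few for a share under 0.05, and the real split gave 5335 genes and the highest other 0.

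TNC alone raised Il6, Ccl2 and Lcn2, as TNF did, and its group carries an ambiguous title. TNF in those cultures would have raised the interferon genes, whose median was -0.215 with TNC and 3.42 with TNF. With TNC present, TNF raised these genes by less. The values therefore argue against TNF at the dose used, and a smaller amount is not excluded. Macrophages in the cultures would have brought Lyz2, C1qa, C1qb, Csf1r, Ctss and Tyrobp (chosen after values were seen). Lyz2, the highest of these relative to the untreated aorta, reached 5.22% of its level there, although Ccl2 and Il6 passed the highest aortic pool (16040 against 4320 and 11340 against 4526), which argues against macrophages. The whole macrophage list had 4 of 20 genes up (median 0.25), Cd14 by 3.58. A bacterial substance carried with the TNC preparation may raise the same genes, and it cannot be told apart from TNC, since the series holds 0 comparisons between preparations. The same limit holds for the effects of TNC under TNF and for the interaction. A direct action of TNC on the cells stays open beside such a substance.

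Neutrophil and chemokine genes were high in the suprarenal KO pool under CaAngII, with CaAngII responses of opposite sign in the genotypes (difference of list medians 7.20 for neutrophils, not tested; Camp, Ltf and Ngp count in WT only, and the median over genes counted in any of the 4 pools was 4.39). Blood of unchanged composition would bring red-cell transcripts by about the neutrophil median, 5.19 over the 5 members counted, which leans toward genes high in KO. The 3 erythroid genes, though, had a median of 0.508 in KO against WT (Alas2 1.88, Hbb-b2 -0.67), and blood richer in neutrophils stays open. Skeletal muscle lists had opposite signs too (5.84 suprarenally and 5.15 infrarenally, not tested), and muscle and neutrophil genes were lower together in untreated KO pools, where muscle stays open. Against the untreated suprarenal WT pool, though, the KO pool under CaAngII held less muscle (median -1.997, 15 of 15 lower) and more neutrophil transcript (median 3.503, 5 of 8 higher), so attached muscle does not account for those 5 genes. With 1 array per condition, a single mouse among the 8 pooled may carry the signal, and this cannot be told apart from an effect of the genotype. The loss of Tnc stays open, untested in single mice.

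Endothelial genes were bright in the smooth muscle cultures: Emcn read 12660 without factors against 1630 in untreated aorta, Pecam1 3216 against 2524 and Cdh5 1795 against 1053. Endothelial cells like those of the aorta would bring their other abundant transcripts, but 5 of 18 members stood more than 8-fold under the level that the share of Pecam1 needs, with Cldn5 41.1-fold, Mmrn2 40.6-fold and Nos3 35.2-fold below the aorta. Other members stood near or above it, among them Eng (2161 against 964), Tie1 (350.5 against 283.8), Flt1 (386.5 against 387.6) and Esam (2052 against 2012). The untreated pools also held brown-fat transcript (Ucp1 5125 to 15020), so their levels need not be those of endothelium in the aorta wall. Endothelial cells changed by culture stay open, and no biological explanation was tested, since the design gives none.

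Single arrays stood apart from the other 3 of their group in 13 of 292 groups of named genes, where 14.6 would by chance, about 1 in 20. The gaps, as shares of the range, were 0.857 for Cemip, 0.873 for Col10a1, 0.917 for Csf3 and 0.834 for Ifit1bl1 with TNC alone. With TNC and TNF they were 0.898 for Arg2, 0.906 for Col4a1, 0.848 for Csf3, 0.862 for Dlx5, 0.919 for Irf1, 0.838 for Sox9, 0.86 for Tnfaip2, 0.923 for Tpm2 and 0.85 for Vnn3.

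The spike-in controls Dap and Thr, outside the main measurement, were high in the untreated infrarenal KO pool. Dap read 2366 against 488 to 799.7 in the other pools, and Thr 602.3 against 123.6 to 206. Among the cell arrays, Dap read 1099 in replicate 1 of TNC with TNF, against 2014 to 2462 in the others.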

How the results depend on the processing

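One alternative, counting in the aorta only genes at or above the 50th percentile in the cells, was chosen after seeing the data, and the others were planned.

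In the cells, 124 of 129 counts under alternatives stayed within 1.5 times the reported count. A 2-fold minimum, which by construction keeps fewer genes, gave the other 5: 1457 for TNF without TNC, 572 for TNF with TNC, 1004 for TNC without TNF, 747 for TNC with TNF and 880 for the interaction. Leaving out each array in turn gave 4570 to 5491, 2638 to 3309, 3970 to 5056, 3294 to 4363 and 2342 to 2801 genes. With the replicate number as a fixed block the counts were 5049, 3069, 4294, 3594 and 2520. With arrays of the same number within a TNC condition taken as the same culture, which no label states, they were 4699, 2591, 4918, 4363 and 2070. Of 6098 values of named genes, 6035 kept their direction and side of the threshold, and 63 kept their direction and no longer passed.

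Centring on the median moved the share of higher calls from 41.2 to 56.1% for TNF without TNC, from 43.3 to 55.1% for TNF with TNC and from 52 to 41.5% for the interaction. For TNC with TNF it moved from 57.7 to 48.1% (2034 higher and 2195 lower). The majority changed side in each of these 4. It moved the median of all genes for TNF without TNC from -0.06 to 0.04. In the aorta it moved the share for the KO infrarenal response from 64.2 to 53.3%, with the median from 0.07 to -0.07 (WT infrarenal 0.00 to -0.10). Quantile normalization moved the share for untreated infrarenal KO against WT from 61 to 50.2% and for the infrarenal genotype difference from 40.9 to 57.5%. Counting only genes at or above the 50th percentile in the cells turned the WT suprarenal response from 33.7 to 53.5% and infrarenal KO against WT under CaAngII from 48.1 to 53.8%.

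Of 175 list results in the cells, 63 passed, against 18 with an estimated correlation. By fry, which tests each list without setting it against other genes, 116 passed. Over all list alternatives 593 of 700 were the same, 59 newly passed and 48 no longer did.

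The aortic counts depend on the filter, which sets how many genes are counted. With no filter they were 2521 (WT suprarenal response), 2744 (KO suprarenal), 4441 (WT infrarenal), 4478 (KO infrarenal), 2331 (KO against WT, untreated suprarenal), 2308 (CaAngII suprarenal), 2357 (untreated infrarenal), 2133 (CaAngII infrarenal), and 3664 and 3455 for the suprarenal and infrarenal genotype difference. Over all 4 pairs they were 104 for the CaAngII response and 28 for KO against WT. With all arrays compared at or above the 50th percentile, the counts were 172, 308 and 1287 for the WT suprarenal, KO suprarenal and KO infrarenal response, 74, 180, 54 and 66 for KO against WT in the same order, 324 and 126 for the genotype differences, and 27 (CaAngII), 1 (KO against WT) and 232 (region) over 4 pairs. Over genes at or above the 50th percentile in the cells they were 185 and 348 for the suprarenal responses, 92, 196, 113 and 52 for KO against WT, 406 and 308 for the genotype differences and 233 for region. On the scale of log2(value + 32), which shrinks ratios of dim genes, the infrarenal genotype difference was 347, and over 4 pairs 40 (CaAngII) and 1 (KO against WT). Of 1437 values of named aortic genes 231 moved by more than the replicate spread in the cells, among them 143 of 225 on the scale of log2(value + 32), so most of these ratios depend on that scale. Of 104 aortic counts 68 stayed within 1.5 times, and of 346 list medians 332 moved under quantile normalization by less than the replicate SD of that list's median in the cells.

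Of 36 list results carried from cells to aorta, 28 were the same, 3 newly lay outside the central 95%, 4 no longer did and 1 changed side: genes TNC raised, for the infrarenal genotype difference, stood at percentile 42.17 with only the 100 genes of lowest p, against 99.98, and the cause was not tested. Dim genes limit the arrays: other probe sets of called genes had the same sign in 84.8 to 88.6%, and bright ones in 96.6 to 99.6%.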

Other observations

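The tests of the 3 hypotheses here were all chosen after the results were seen.

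Adrenal and fat genes varied between aortic pools as well. The pools may differ in the tissue taken with the aorta. With 1 pool per condition, this cannot be told apart from an effect of genotype or treatment. That limit holds for the list medians and 2-fold counts of the aorta too. The steroid gene Hsd3b1 read 1425 in the WT suprarenal pool under CaAngII and 5.243 without treatment, and Cyp11b1 376 and 51.9, and the mast cell gene Mcpt4 was higher suprarenally by 1.27 in WT and 1.36 in KO, against -0.67 and -0.23 infrarenally. In the infrarenal pools Hsd3b1 was higher in KO than in WT both without treatment (2613 against 8.751) and under CaAngII (181.9 against 6.077). The brown-fat gene Cidea was at -3.10 in WT and -2.70 in KO infrarenally under CaAngII, and Pdk4 at -1.74 and -1.68.

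TNF raised 672 genes at least 2-fold without TNC, and 478 of them (71.1%) had a TNF effect called smaller with TNC. A candidate explanation is that TNC alone had already raised these genes. Among the 397 that TNC also raised, 326 (82.1%) had a smaller effect. Among the 275 that TNC had not raised, 152 (55.3%) did too, and their median TNF effect was 1.88 without TNC and 0.76 with it. Choosing genes by a large TNF effect itself favours a smaller one with TNC. In 50 simulations with the same TNF effect on both sides, at most 3.89% of such genes were called smaller at the same p, and the medians were 1.96 and 1.6. A prior rise under TNC therefore leaves part of the pattern open.

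Alad, which differed between genotypes in all 4 pairs (0.75 to 1.29), lies within 5 Mb of Tnc, where DNA of another mouse strain may remain around the targeted gene. With Alad, which prompted the test, left out, 1 of 30 genes there (3.33%) differed by at least 0.3 the same way in all 4 pairs, Hdhd3 (0.32 to 1.08, chosen after values were seen), against 0.31% of 12600 other genes (Fisher p = 0.0909). These genes are too few to decide.

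The clock-controlled gene Dbp read 618.3 and 548.7 in the suprarenal and infrarenal KO pools under CaAngII, against 4858 and 3193 in the matching WT pools (log2 -2.97 and -2.54), while the untreated pools differed by 0.00 and 0.13. Nr1d1 stood at -1.33 and -1.28. Nr1d2 stood at -1.498 and -1.125, and Per3 at -1.435 and -1.492 (both chosen after values were seen). Untreated, Nr1d2 differed by 0.144 and 0.195 and Per3 by 0.29 and 0.031, but Nr1d1 by -0.423 and -0.376. Per2 and Tef, expected low as well, stood at only -0.43 and 0.04, and at -0.88 and -0.43 (Tef chosen after values were seen). Collection at another time of day would move genes of the opposite phase the other way, and the median of Arntl and Npas2 (chosen after values were seen) was 0.982: Arntl 1.25 and 0.67, Npas2 0.71 and 1.35. Untreated, Arntl differed by 0.364 and -0.46 and Npas2 by -0.912 and 0.033. Within WT, CaAngII moved such genes the same way infrarenally: Dbp from 8340 to 3193, Per3 from 1531 to 640.5 and Per2 from 1279 to 338.3. Arntl went from 267.3 to 456.4 and Npas2 from 79.45 to 312.3. A different hour of collection for the KO mice under CaAngII may contribute to their differences from WT. It cannot be told apart from a larger response of these genes to CaAngII in KO. Per2 gives the reading of another hour little support, while Nr1d2 and Per3 go with it. An effect of Tnc loss or of inflammation on the clock was not tested.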
